A study of Arabidopsis thaliana with 14 samples.

How the data were processed

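RNA from Arabidopsis thaliana root tips was measured on Affymetrix ATH1 arrays, which carry short probes grouped into probe sets, with 1 labelled sample per array. The deposited table holds 22810 probe sets on 14 arrays, and all of its columns were used. Per the labels, the authors processed the arrays with MAS5 and GCOS; the versions and settings are not given in the sources used here. The deposited values are signal intensity on a linear scale, and the mean of each array after trimming 2% of its values at each end was 100, so that no further normalization between arrays was applied. Equal trimmed means do not show that the arrays were alike otherwise: the median signal was highest in the control 24 h arrays (42.4 and 40.5) and as low as 35.4 elsewhere. The number of arrays per group, 2 or 3, limits the precision of every value. Nothing in the sources used here says that replicates were separate cultures, so the spread is that between samples.

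Probe sets were paired with genes through the reference files: 13513 with 1 gene, 503 with several genes and 8794 with no gene named. Unnamed probe sets were tested and are given by their identifiers, and no gene was assigned to them from elsewhere. IPT8, the gene that the labels name in this line, has no named probe set, so its level was not analysed here; whether 1 of the unnamed probe sets measures it is not known from the sources used here. The 64 control probe sets were left out of the tests and used as measures of RNA quality. A gene table of the reference assembly TAIR10.1 served only for names and for the order of genes along chromosomes; no coordinates are printed, because the labels state no build.

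Values were analysed as log2 of the signal plus 6.3, which is the 20th percentile of all values. Folds are ratios on this scale and so understate the ratio of dim signals. A probe set was kept where at least 2 arrays exceeded 23, the 40th percentile of all values, which left 15605 probe sets, of which 8527 have 1 gene, 307 several and 6771 none. With R 4.3.3 and limma 3.58.1, 1 mean per group was fitted to all 14 arrays of the 6 groups. Variances were moderated with an intensity trend (8 residual and 5.96 prior degrees of freedom). A probe set was called at a Benjamini-Hochberg adjusted p under 0.05 over all probe sets kept, in a two-sided test. The 9 comparisons were 4 against the control of the same time, 2 between the treatments, 1 between the control groups, and 2 interactions that test whether the effect of a treatment differed between 24 h and 12 h. All adjusted p-values of genes below are from limma. Errors of log2 changes are standard errors (SE), and errors of signals are standard deviations (SD).

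The design, the tests, the gene lists, the rule for named genes and most of the alternatives were chosen before the data were examined. Named genes are, per comparison, the 5 risen and the 5 fallen with the largest fold among called probe sets that pair with exactly 1 gene and whose arrays do not overlap between the groups (for interactions, among the called). For the 4 comparisons with control, up to 4 members with the lowest p were added from each list with a called member, called or not. IPT8 was also part of the rule. Any other probe set or gene named below was chosen after its values were seen. Of 25 gene lists with 302 genes, 35 genes have a named probe set and 26 were measured, so that 12 lists had no measured member and 9 had at least 2. Those 9 lists were tested with camera of limma, 1 probe set per gene, at its preset correlation of 0.01 and again with an estimated correlation, adjusted over 36 tests. A list result covers only the measured members, such as 2 of 10 listed type-A response regulators and 2 of 9 lateral root founder genes. It uses the same values as the calls of those members and is no separate evidence. After the results were seen, 19 gene families were added (133 tests, at least 7 members each).

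Overlaps of calls were set beside the number given by independence and beside 100 simulations of unchanged groups that share their control arrays. Replicate numbers were checked for pairing: of 31 same-numbered pairs of residuals between groups, 3 correlated at r over 0.1, in a range from -0.27 to 0.19. The pairs are not all separate values, because residuals in a group of 2 mirror each other. Replicates 1 and 2 of 2 such groups give the same r, as for estradiol 24 h with trans-zeatin 24 h (0.15 in both). The numbers were therefore not used as pairs, and a fit with the number as a block was an alternative. The method was tested on simulated data of the same design with 100 probe sets changed 2-fold and 100 changed 4-fold. It recovered from 16 to 74% of the former and from 78 to 96% of the latter, depending on the comparison, and from 2.82 to 8.75% of its calls were false. The simulated comparisons gave from 107 to 179 calls each. Where a real comparison gave fewer, its threshold was stricter, and these shares overstate what it could recover. In simulated lists of 8 independent members, camera gave an unadjusted p under 0.05 for 100% of those shifted by 1 log2 unit and 6% of those not shifted. With 2, 3 or 5 members, the sizes measured here, it did so for 100% of the shifted lists and 4, 9 and 8% of the others; this simulation was added after the results were seen. The count of neighbouring genes was compared with 10000 random placements. In simulated orders of 3000 genes, all adjacent and with fewer placements each, it was high at an unadjusted p under 0.05 in 3% with nothing planted. With 15 planted pairs it was so in 100%.

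The alternatives were quantile normalization, centring each array on its median, no pseudocount or one at the 40th percentile, no filter or a stricter one, no intensity trend, a replicate block, and only the arrays of the time point. Further ones left out probe sets of shared sequence (_s_at and _x_at), asked for at least 2-fold, estimated the correlation in list tests, or left out each of the 14 arrays in turn. The 3 alternatives added after seeing the data left out both 12 h arrays that stood apart, or took as a covariate the 25S rRNA signal or the 3'/5' ratio, as the mean log2 ratio of actin, GAPDH and ubiquitin.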

Results

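The series profiled transcripts in the primary root apex of Arabidopsis thaliana, on the subject of crosstalk between auxin and cytokinin. Root tips of 5 mm were taken from seedlings of the line AtIPT8/pga22 in the Wassilewskija background after 7 days on plates. The line is known as one in which estradiol switches on IPT8, an isopentenyltransferase that makes cytokinin; the labels also describe it as a T-DNA knock-out of IPT8. Seedlings were covered with liquid medium alone, with 5 µM 17-beta-estradiol or with 5 µM trans-zeatin, a cytokinin, for 12 or 24 h. There were 3 arrays each of control and estradiol at 12 h, and 2 arrays each of trans-zeatin at 12 h and of control, estradiol and trans-zeatin at 24 h. The median signal per array ranged from 35.4 to 42.4 and the maximum from 6938 to 10280. Spearman's rho ranged from 0.929 to 0.968 between replicates and from 0.884 to 0.962 between arrays of different groups.

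The first principal component held 27.2% of the variance and separated all control arrays from all treated arrays. On the second, control 12 h replicate 3 (37.06) and estradiol 12 h replicate 1 (32.04) stood apart from the other arrays. RNA quality moved with treatment: the signal ratio of the 3' to the 5' actin control probe sets was 6.24 and 6.44 in the control 24 h arrays and from 3.71 to 4.85 in the treated 24 h arrays. At 12 h it ranged from 3.23 to 4.93 in control and from 2.37 to 3.31 in treated arrays. Over both times the ratio was 1.44 times as high in the 5 control arrays as in the 9 treated arrays (exact permutation test within time points, two-sided, 840 arrangements, p = 0.0024, adjusted over 2 measures 0.0036). The mean over actin, GAPDH and ubiquitin differed 1.23-fold in the same direction (exact permutation p = 0.0036).

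**Figure D1:**
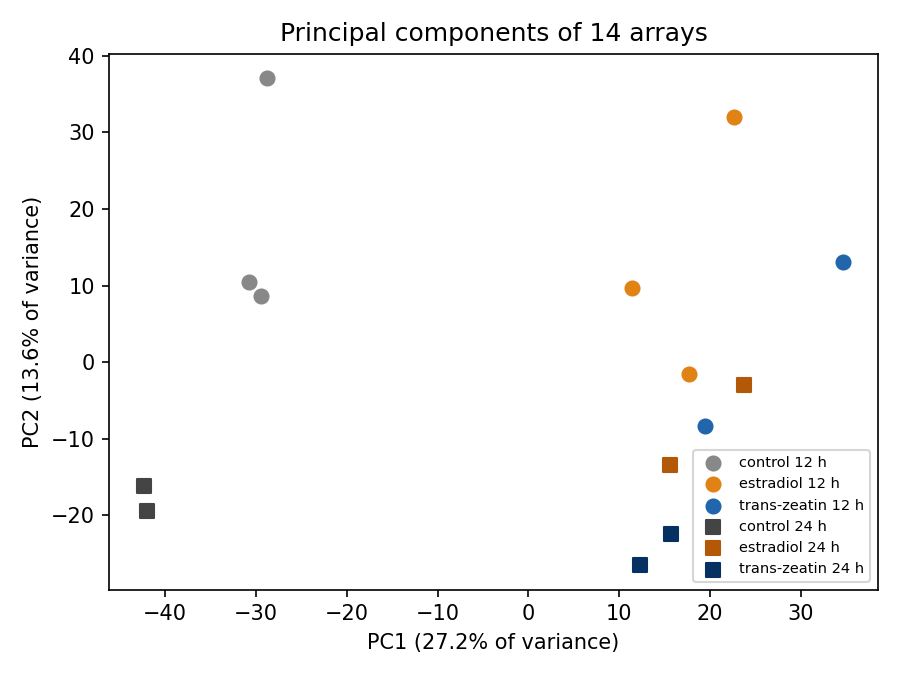
Principal components of the 14 arrays, computed from log2 values. Each point is 1 array, PC1 (27.2% of the variance) is on the x axis and PC2 (13.6%) on the y axis, in arbitrary units; colour and shape give the group. The control arrays lie on the left and the treated arrays on the right, and control 12 h replicate 3 and estradiol 12 h replicate 1 lie highest on PC2.

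The first comparison asked what changed after 12 h of estradiol, when IPT8 is to be induced. All 14 arrays are of this line and IPT8 was not read, so effects of estradiol itself cannot be told apart from those of IPT8. ARR16 (listed as RR16), a type-A response regulator and primary cytokinin response gene, rose 6.21-fold, from a signal of 7.74 ± 3.36 (SD, n = 3) to 81.3 ± 23.1 (n = 3; adjusted p = 1.9e-05). AT3G28320 rose 8.46-fold (log2 change 3.08 ± 0.22 SE, adjusted p = 3e-06). AT4G11190, a dirigent-like protein gene, rose 10.1-fold (3.33 ± 0.41), and AT4G16000, AT4G35725 and the glutaredoxin gene ROXY2 rose 9.78-, 8.24- and 7.87-fold. ATC, a relative of the flowering regulator TFL1, fell by 4.72 ± 0.46 on the log2 scale, from a signal of 1100 ± 200 to 40.7 ± 26.3 (adjusted p = 6.5e-05). AT5G10130 (-3.22 ± 0.20), AT4G00670 (-3.42 ± 0.42), AT5G60520 (-3.04 ± 0.39) and AT4G14020 (-2.61 ± 0.42) also fell. The probe set with the largest rise, 257039_at, has no gene named here and was chosen after its values were seen. Its signal was 1700 ± 271 with estradiol and 11.4 ± 4.2 in control (97.5-fold, adjusted p = 1.3e-09).

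Both measured type-A response regulators were called at estradiol 12 h, ARR15 with a log2 change of 1.32 ± 0.34 (adjusted p = 0.04). Adjusted over the list alone, 2 of 2 passed, and as a list they shifted up (median log2 1.98, camera adjusted p = 5e-04; adjusted p = 0.044 with an estimated correlation). Of 5 measured genes of auxin conjugation and oxidation, 1 rose, 1 fell and 3 did not pass. AT1G14120, listed as DAO2 beside the auxin oxidase gene DAO1, rose 3.71-fold (1.89 ± 0.43, adjusted p = 0.022). WES1 (GH3.5), which joins auxin to amino acids, fell by 0.91 ± 0.19 (adjusted p = 0.016). GH3.3 (-0.98 ± 0.42) and DAO1, AT1G14130 (0.27 ± 0.17), did not pass. Adjusted over the list alone 2 of 5 passed, and the list test did not pass (adjusted p = 0.94). IAA30, of the Aux/IAA repressors of auxin response, rose 1.98-fold (adjusted p = 0.028) while IAA18 was at -0.14 ± 0.23. Here 1 of 2 passed adjusted over the list alone, and the list test did not pass (adjusted p = 0.38). The tryptophan synthesis gene AT2G04400 (IGPS), the only measured member of its list, rose 1.72-fold (adjusted p = 0.031), and 1 of 1 passed adjusted over the list alone. Leaving out single arrays ended the call of ARR15 (control replicate 1 or 3, estradiol replicate 1 or 2, or any 24 h estradiol or trans-zeatin array; adjusted p 0.059 to 0.13) and of AT1G14120 (control replicate 1 or 2, estradiol replicate 1 or 3; 0.052 to 0.086). It also ended that of IAA30 (control replicate 1 or 3, estradiol replicate 2 or 3; 0.068 to 0.1), of AT2G04400 (control replicate 1 or 2, estradiol replicate 1; 0.077 to 0.11) and of WES1 (control replicate 1 or 2; 0.056 to 0.063). Other settings ended the calls of ARR15 (quantile normalization, no pseudocount, no filter, only the 12 h arrays, or without both arrays that stand apart; adjusted p 0.051 to 0.22). So they did for IAA30 (no filter, replicate block, only the 12 h arrays, or without both arrays; 0.051 to 0.073) and AT2G04400 (no intensity trend, replicate block, only the 12 h arrays, or without both arrays; 0.056 to 0.095). Those of AT1G14120 (0.078) and WES1 (0.066) ended with only the 12 h arrays. Taking the 3'/5' ratio as a covariate ended 4 of these calls. AT1G14120 was then at 0.91 ± 0.38 (adjusted p = 0.24) and WES1 at -0.61 ± 0.22 (0.18), which are smaller changes. IAA30 was at 1.15 ± 0.31 (0.073; 0.98 ± 0.24 before) and AT2G04400 at 0.76 ± 0.25 (0.15; 0.78 ± 0.19 before), with larger errors.

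In all, 762 of 15605 probe sets were called at estradiol 12 h, 368 higher and 394 lower, of which 197 and 151 changed at least 2-fold. Of these, 382 have 1 gene named. No member passed over all probe sets in the lists of cytokinin removal (2 measured, median log2 0.26, adjusted p = 0.38), auxin synthesis (2, 0.31, 0.66), mitosis (2, -0.52, 0.11), root meristem regulators (3, -0.42, 0.53), root hair cells (2, -0.19, 0.7) and lateral root founder genes (2, -0.77, 0.063). Adjusted over the list alone 1 of 2, 0 of 2, 2 of 2, 1 of 3, 0 of 2 and 2 of 2 passed. The lateral root founder list passed without control replicate 3 (adjusted p = 0.022), estradiol replicate 1 (0.029) or trans-zeatin 24 h replicate 1 (0.036) or 2 (0.033); with all arrays it had adjusted p = 0.31 with an estimated correlation. The only measured genes of the DNA replication, low oxygen and circadian clock lists (PRL, AT4G17260 and GI) had log2 changes of -0.25, -0.03 and -0.29, and 0 of these 3 were called over all probe sets or adjusted over the list alone. The count was 417 and 459 without control replicate 1 or 2, 502 and 505 without estradiol replicate 1 or 3, 332 with only the 12 h arrays, 426 without both arrays that stand apart, and 355 with the 3'/5' ratio as a covariate.

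The next comparison asked what applied cytokinin changed in 12 h. ARR16 rose 5.63-fold, to a signal of 71.5 ± 7.58 (n = 2; control 7.74 ± 3.36, n = 3; adjusted p = 8e-05). AT4G16000 rose 15.8-fold (log2 change 3.99 ± 0.34 SE, adjusted p = 1.7e-05), AT3G28320 10.7-fold (3.41 ± 0.24), its neighbour AT3G28310 10.4-fold (3.37 ± 0.29), AT5G26260 11-fold (3.46 ± 0.29) and AT4G11190 10.1-fold (3.33 ± 0.46). ATC fell by 4.53 ± 0.52 (adjusted p = 0.00022) and AT5G10130 by 4.10 ± 0.22 (adjusted p = 6.1e-07), from a signal of 381 ± 135 to 15.4 ± 0.684. AT4G00670 (-3.55 ± 0.47), AT5G60520 (-3.51 ± 0.44) and AT3G53980 (-3.07 ± 0.57) fell as well. The probe set 257039_at was at 15.2 ± 1.66 with trans-zeatin (1.24-fold, adjusted p = 0.52).

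ARR15 was at 1.29 ± 0.38 with trans-zeatin at 12 h (adjusted p = 0.055), so that 1 of 2 type-A response regulators passed over all probe sets and 2 of 2 adjusted over the list alone. The list shifted up at the preset correlation (median log2 1.89, adjusted p = 0.0019), with adjusted p = 0.057 with an estimated correlation. AT1G14120 rose 4.18-fold (adjusted p = 0.02), and the other named genes of auxin conjugation and oxidation, AT1G14130 (0.65 ± 0.19), WES1 (-0.52 ± 0.22) and GH3.17 (0.49 ± 0.33), did not pass; 2 of 5 did adjusted over the list alone (list adjusted p = 0.21). IAA30 rose 2.07-fold (adjusted p = 0.029) with IAA18 at 0.39 ± 0.26 (1 of 2 adjusted over the list alone, list adjusted p = 0.11). Of the lateral root founder genes, PUCHI, a transcription factor of early lateral root primordia, fell by 1.55 ± 0.29 (adjusted p = 0.0074), and LBD16, which acts in lateral root initiation, was at -0.65 ± 0.24 (adjusted p = 0.11). Adjusted over the list alone 2 of 2 passed, and the list shifted down (median -1.10, adjusted p = 0.046; adjusted p = 0.28 with an estimated correlation). That list call also ended without control replicate 1 or 2, trans-zeatin replicate 1 or 2, estradiol 12 h replicate 3, either control 24 h array or estradiol 24 h replicate 1 (adjusted p 0.051 to 0.1), and with the 3'/5' ratio (0.26) or the 25S rRNA signal (0.1) as a covariate. AUR2, a mitotic kinase, fell by 0.82 ± 0.23 (adjusted p = 0.043) and AUR1 was at -0.71 ± 0.21 (2 of 2 adjusted over the list alone, list adjusted p = 0.063). AT4G17260, a lactate dehydrogenase gene of the low oxygen list, fell by 0.92 ± 0.24 (adjusted p = 0.036; 1 of 1 adjusted over the list alone). Leaving out single arrays ended the calls of AUR2 (any 12 h control or trans-zeatin array, or any 24 h control or trans-zeatin array; adjusted p 0.051 to 0.3) and AT4G17260 (any 12 h control or trans-zeatin array, or any 24 h control array; 0.053 to 0.21). It also ended those of IAA30 (control replicate 1 or 3, trans-zeatin replicate 1 or 2; 0.063 to 0.16), AT1G14120 (control replicate 1 or 2, trans-zeatin replicate 2; 0.057 to 0.21) and PUCHI (trans-zeatin replicate 2; 0.086). Other settings ended the calls of AUR2 (quantile normalization, centred arrays, no filter, replicate block, only the 12 h arrays, or without both arrays that stand apart; adjusted p 0.052 to 0.098) and AT4G17260 (centred arrays, no filter, no intensity trend, replicate block or only the 12 h arrays; 0.052 to 0.096). Those of IAA30 (no filter, replicate block, only the 12 h arrays, or without both arrays; 0.057 to 0.067) and AT1G14120 (only the 12 h arrays; 0.068) ended as well. The 25S rRNA signal as a covariate ended those of AUR2 (0.16), AT4G17260 (0.16) and AT1G14120 (0.12). The 3'/5' ratio as a covariate ended calls where the change was smaller and its error larger, as for AT1G14120 at 0.23 ± 0.55 (adjusted p = 0.9; 2.06 ± 0.48 before), AUR2 at -0.44 ± 0.37 (0.64), AT4G17260 at -0.75 ± 0.42 (0.44), PUCHI at -1.22 ± 0.50 (0.28) and AT4G11190 at 2.37 ± 0.73 (0.15). They also ended where the change was larger, for IAA30 at 1.36 ± 0.45 (0.18; 1.05 ± 0.26 before) and AT3G53980 at -3.74 ± 0.97 (0.1).

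At trans-zeatin 12 h, 1176 probe sets were called, 501 higher and 675 lower, with 281 and 273 of them changed at least 2-fold; with each array centred on its median the majority turned, to 575 higher and 532 lower. No list member passed over all probe sets in cytokinin removal (median log2 0.26, adjusted p = 0.39), auxin synthesis (-0.20, 0.87), root meristem regulators (-0.26, 0.87) and root hair cells (-0.38, 0.53); 1 of 2, 0 of 2, 0 of 3 and 0 of 2 passed adjusted over the list alone. The single genes of tryptophan synthesis (AT2G04400, 0.19), DNA replication (PRL, -0.39) and the circadian clock (GI, 0.10) were not called over all probe sets; PRL passed adjusted over the list alone (1 of 1). The count was 264 without trans-zeatin replicate 2, 612, 769 and 770 without control replicate 1, 2 or 3, 500 with only the 12 h arrays, and 112 with the 3'/5' ratio or 521 with the 25S rRNA signal as a covariate.

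After 24 h of estradiol, ARR16 rose 8.93-fold, from a signal of 6.21 ± 1.36 to 105 ± 12.3 (n = 2 each; adjusted p = 1.7e-05), and ARR15 5.09-fold (log2 change 2.35 ± 0.42 SE, adjusted p = 0.0056). AT4G11190 rose 35.5-fold (5.15 ± 0.50, adjusted p = 4.9e-05), AT3G28320 24.4-fold (4.61 ± 0.27), AT5G26260 21.5-fold (4.43 ± 0.32), AT2G19970 20-fold (4.32 ± 0.71) and AT1G31710, a copper amine oxidase gene, 11.3-fold (3.49 ± 0.52). ATC fell by 5.85 ± 0.57, from 1100 ± 254 to 12.6 ± 2.6 (adjusted p = 4.9e-05). AT5G60520 (-3.71 ± 0.48), AT5G54370 (-3.60 ± 0.40), AT3G53980 (-3.31 ± 0.62) and AT5G10130 (-2.97 ± 0.25) fell too. The unnamed 257039_at reached 1980 ± 296 against 6.31 ± 3.73 in control (161-fold, adjusted p = 4.9e-09).

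Of the lists at estradiol 24 h, the 2 measured of 10 listed type-A response regulators shifted up (2 of 2 called, 2 of 2 adjusted over the list alone, median log2 2.75, adjusted p = 3.8e-05; adjusted p = 0.025 with an estimated correlation). The 2 measured of 9 listed lateral root founder genes shifted down (2 of 2 called, 2 of 2 adjusted over the list alone, median -1.48, adjusted p = 0.0049), with adjusted p = 0.12 with an estimated correlation. PUCHI fell by 1.66 ± 0.32 (adjusted p = 0.01) and LBD16 by 1.3 ± 0.26 (adjusted p = 0.012). AT1G14120 rose 7.63-fold (2.93 ± 0.53, adjusted p = 0.0059), while WES1 (-0.82 ± 0.24, adjusted p = 0.072), AT1G14130 (-0.36 ± 0.21) and GH3.17 (0.43 ± 0.36) did not pass (2 of 5 adjusted over the list alone, list adjusted p = 0.53). PRL (MCM7), a subunit of the replication helicase, fell by 0.95 ± 0.19 (adjusted p = 0.011; 1 of 1 adjusted over the list alone). Leaving out single arrays ended the calls of ARR15 (control replicate 1 or estradiol replicate 2; adjusted p 0.055 to 0.057), AT1G14120 (control replicate 2; 0.061), PUCHI (control replicate 1 or 2, estradiol replicate 2; 0.061 to 0.1), LBD16 (control replicate 2 or estradiol replicate 2; 0.1 to 0.12), PRL (any array of the 2 groups; 0.059 to 0.081) and AT3G53980 (control replicate 1 or 2, estradiol replicate 2; 0.057 to 0.11). Without a pseudocount the call of AT3G53980 ended (adjusted p = 0.051). Taking the 3'/5' ratio as a covariate ended the calls of PUCHI at -1.49 ± 0.38 (adjusted p = 0.064), LBD16 at -1.13 ± 0.30 (0.074) and PRL at -0.86 ± 0.22 (0.062).

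At estradiol 24 h, 595 probe sets were called, 356 higher and 239 lower, with 302 and 181 changed at least 2-fold. With each array centred on its median the split was 472 higher and 155 lower: the centring moved the median over all probe sets from -0.0938 to 0.0153 in this comparison, from 0.0592 to -0.0526 between the controls and from -0.0535 to 0.0603 in the estradiol interaction. No member passed over all probe sets in the lists of cytokinin removal (median log2 -0.13, adjusted p = 0.87), auxin synthesis (0.69, 0.38), Aux/IAA repressors (0.45, 0.26), mitosis (-0.73, 0.085), root meristem regulators (0.11, 0.38) and root hair cells (0.36, 0.39); 0 of 2, 0 of 2, 1 of 2, 2 of 2, 1 of 3 and 0 of 2 did adjusted over the list alone. The mitosis list passed without estradiol replicate 2 (median -0.91, adjusted p = 0.033); with all arrays it had adjusted p = 0.38 with an estimated correlation. AT2G04400 (0.73), AT4G17260 (0.12) and GI (-0.82) were not called over all probe sets, while AT2G04400 and GI, each the single measured gene of its list, passed adjusted over the list alone (1 of 1 each). The count was 204 and 233 without control replicate 1 or 2, 198 without estradiol replicate 2, and 349 with the 3'/5' ratio, which was higher in these controls, as a covariate. It was 1158 with only the 24 h arrays and 939 without both 12 h arrays that stand apart.

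After 24 h of trans-zeatin, ARR16 rose 7.42-fold to a signal of 86.2 ± 1.77 (n = 2; adjusted p = 3.8e-05) and ARR15 5.3-fold (log2 change 2.40 ± 0.42 SE, adjusted p = 0.0048). AT4G11190 rose 51.9-fold (5.70 ± 0.50, adjusted p = 2.2e-05), AT3G28320 46.8-fold (5.55 ± 0.27, adjusted p = 1e-07), AT5G26260 27.2-fold (4.77 ± 0.32), AT3G28310 17.5-fold (4.13 ± 0.32) and AT5G37990 12.2-fold (3.61 ± 0.40). ATC fell by 6.22 ± 0.57 to 10.3 ± 10.9 (adjusted p = 3.1e-05). AT3G53980 (-4.52 ± 0.62), AT5G60520 (-3.49 ± 0.48), AT4G00670 (-3.37 ± 0.51) and AT4G14020 (-3.07 ± 0.51) fell. The probe set 257039_at was at 13.6 ± 5.54 (1.58-fold, adjusted p = 0.24).

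PUCHI fell by 2.22 ± 0.32 (adjusted p = 0.0012) and LBD16 by 1.59 ± 0.26 (adjusted p = 0.0031) at trans-zeatin 24 h. As a list, these 2 measured of 9 listed lateral root founder genes shifted down (2 of 2 called and 2 of 2 adjusted over the list alone, median log2 -1.90, adjusted p = 5e-04), with adjusted p = 0.062 with an estimated correlation. The 2 measured of 10 listed type-A response regulators shifted up (2 of 2 called, 2 of 2 adjusted over the list alone, median 2.65, adjusted p = 3.8e-05; adjusted p = 0.025 with an estimated correlation). AT1G14120 rose 8.91-fold (adjusted p = 0.0037), and WES1 (-0.83 ± 0.24, adjusted p = 0.075), GH3.17 (0.51 ± 0.36) and AT1G14130 (0.23 ± 0.21) did not pass (2 of 5 adjusted over the list alone, list adjusted p = 0.31). Leaving out single arrays ended the calls of ARR15 (control replicate 1 or trans-zeatin replicate 1; adjusted p 0.05 to 0.058), AT1G14120 (trans-zeatin replicate 1; 0.068) and AT4G14020 (control replicate 1; 0.053). With the 3'/5' ratio as a covariate calls ended of PUCHI at -1.96 ± 0.44 (adjusted p = 0.056), LBD16 at -1.32 ± 0.35 (0.11) and AT1G14120 at 1.77 ± 0.49 (0.13; 3.16 ± 0.53 before).

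At trans-zeatin 24 h, 541 probe sets were called, 335 higher and 206 lower, with 270 and 173 changed at least 2-fold; with each array centred on its median the split was 434 and 160. No member passed over all probe sets in cytokinin removal (median log2 -0.07 although camera's direction was up, adjusted p = 0.91), auxin synthesis (0.55, 0.61), Aux/IAA repressors (0.49, 0.26), mitosis (-0.53, 0.21), root meristem regulators (0.05, 0.5) and root hair cells (0.55, 0.26); 0 of 2, 0 of 2, 1 of 2, 1 of 2, 0 of 3 and 0 of 2 did adjusted over the list alone. AT2G04400 (0.43), PRL (-0.46), AT4G17260 (-0.45) and GI (-0.24) were not called over all probe sets, and of these only PRL passed adjusted over the list alone (1 of 1). The count was 213 and 216 without control replicate 1 or 2, 164 and 250 without trans-zeatin replicate 1 or 2, and 176 with the 3'/5' ratio, which was higher in these controls, as a covariate. It was 942 with only the 24 h arrays and 822 without both 12 h arrays that stand apart.

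**Figure D2:**
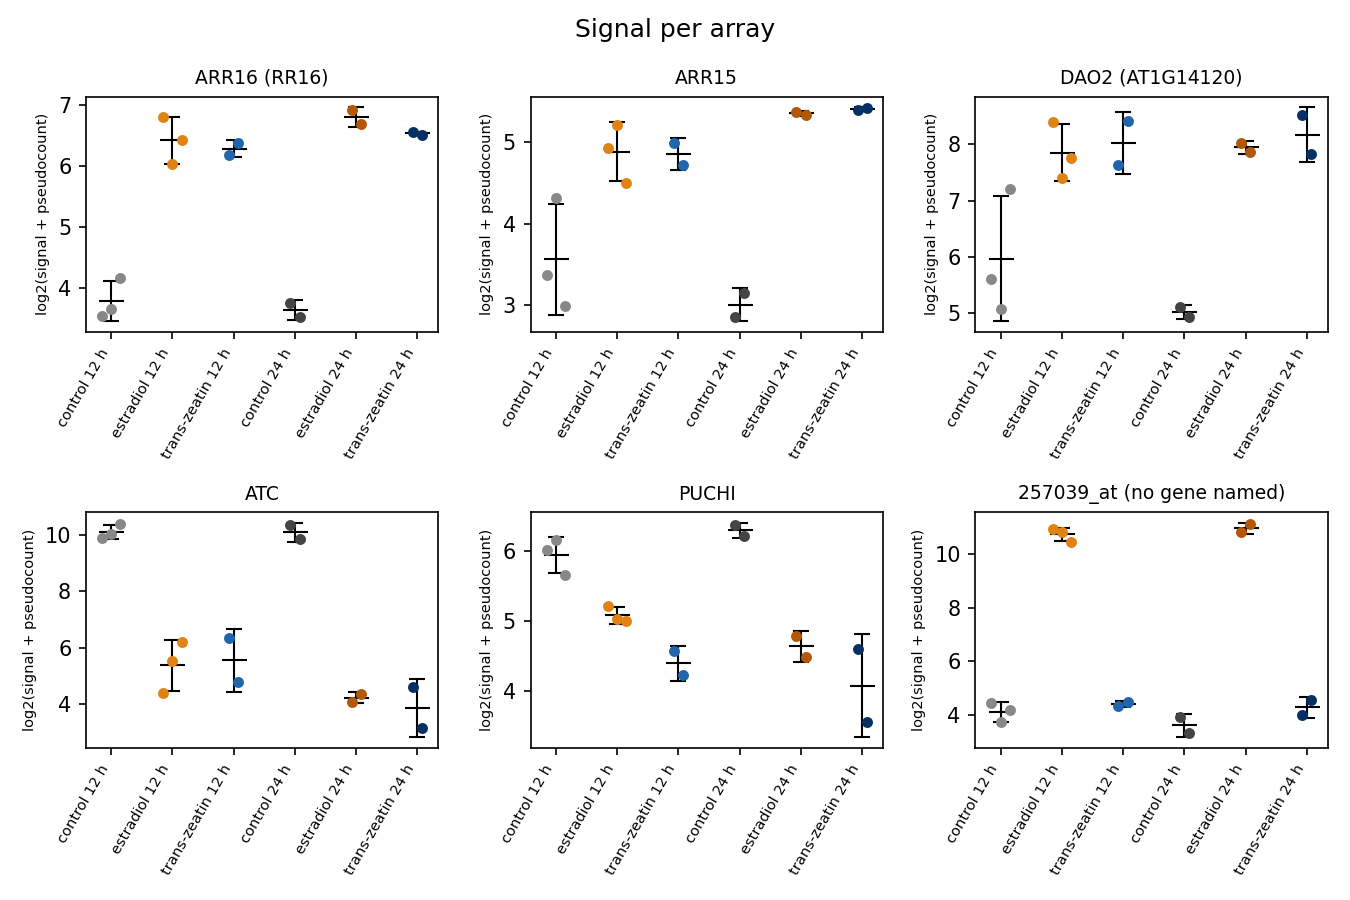
Signal of 6 probe sets on each array, as log2 of the signal plus 6.3 on the y axis, by group on the x axis. Points are arrays, horizontal marks are group means and bars are 1 SD (n = 2 or 3). ARR16 lies higher and ATC lower in every treated array than in every control array, and 257039_at is high in the estradiol arrays, where its signal averaged 1700 at 12 h and 1980 at 24 h.

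The responses to estradiol and to trans-zeatin were then compared. At each time, genes called with both treatments changed in the same direction: 510 probe sets at 12 h (244 higher, 266 lower; 11.8 and 17 given by independence) and 334 at 24 h (241 higher, 93 lower; 7.64 and 3.16). The treatments share control arrays. Simulations of unchanged groups with shared controls and independent noise per probe set gave at most 2 shared calls at 12 h and 1 at 24 h. With nothing changed hardly any probe set is called, so these counts were low by construction. They do not show how much of the overlap the shared controls create. Across probe sets, which are not independent replicates, the correlation of the log2 changes was 0.75 at 12 h and 0.78 at 24 h, against 0.45 and 0.50 in the simulations. The covariance exceeded the simulated one by 0.151 and 0.202. The control groups are too small to give each treatment its own 2 arrays, so part of this overlap can come from the shared controls. The overlap at 12 h was 276, 323, 334 and 197 without control replicate 1, control replicate 2, estradiol replicate 3 or trans-zeatin replicate 2. That at 24 h was 141, 145, 211, 158, 142 and 194 without control replicate 1 or 2, estradiol replicate 1 or 2, or trans-zeatin replicate 1 or 2. With only the arrays of the time point they were 222 and 620, without both arrays that stand apart 331 and 524, and with the 3'/5' ratio as a covariate 99 and 140; the 25S rRNA signal as a covariate gave 329 at 12 h.

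Calls from different times are not independent, because all comparisons share 1 estimate of the spread per probe set. The 3'/5' ratio was also higher in the controls at both times. In pairs of comparisons from different times the group means come from different arrays. There, 243 probe sets were called in the same direction with estradiol at both times (162 higher, 81 lower; 8.4 and 6.03 given by independence) and 297 with trans-zeatin (188 and 109; 10.8 and 8.91). Between estradiol 12 h and trans-zeatin 24 h the overlap was 246 (164 and 82; 7.9 and 5.2), and between trans-zeatin 12 h and estradiol 24 h it was 284 (175 and 109; 11.4 and 10.3), with 1 probe set called in opposite directions. All 4 comparisons shared 131 higher and 53 lower probe sets, of which 53 and 32 have 1 gene named. Among them were ARR16, AT1G14120, AT3G28310, AT3G28320, AT4G11190, AT4G16000, AT4G35725, AT5G26260 and ROXY2, higher, and ATC, AT4G00670, AT4G14020, AT5G10130, AT5G54370 and AT5G60520, lower. Without control 24 h replicate 1 or 2 the estradiol overlap was 125 or 118, and without estradiol 24 h replicate 1 or 2 it was 151 or 118. The trans-zeatin overlap was 166 without trans-zeatin 12 h replicate 2, 149 and 138 without control 24 h replicate 1 or 2, and 133 and 162 without trans-zeatin 24 h replicate 1 or 2. The overlap of estradiol 12 h and trans-zeatin 24 h was 130 and 116 without control 24 h replicate 1 or 2, and 113 and 132 without trans-zeatin 24 h replicate 1 or 2. The remaining overlap was 177 without control 12 h replicate 1, 149 without trans-zeatin 12 h replicate 2, 135 and 131 without control 24 h replicate 1 or 2, and 180 and 124 without estradiol 24 h replicate 1 or 2. With the 3'/5' ratio as a covariate the 4 overlaps were 138, 69, 107 and 70, in the order given above.

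**Figure D3:**
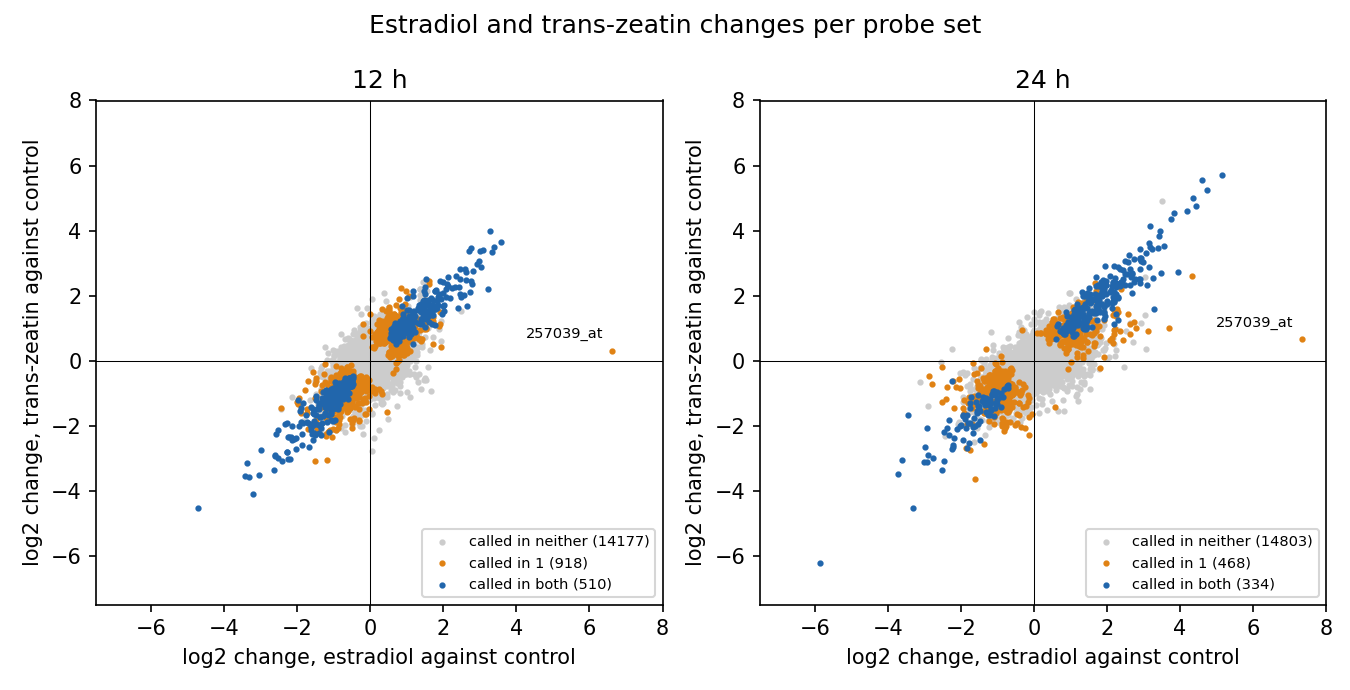
Log2 change with trans-zeatin (y axis) against log2 change with estradiol (x axis), each against the control of the same time, at 12 h (left) and 24 h (right). Points are the 15605 probe sets, coloured by whether they were called in neither, 1 or both comparisons (510 in both at 12 h, 334 at 24 h). The probe set 257039_at lies far along the estradiol axis at both times.

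Estradiol and trans-zeatin were also tested directly against each other. With no other line sampled, a difference can also come from estradiol itself. At 12 h the only probe set called was the unnamed 257039_at, 78.9-fold higher with estradiol (log2 difference 6.30 ± 0.26 SE, n = 3 and 2, adjusted p = 1.1e-08); 1322 probe sets had an unadjusted limma p under 0.05. ARR16 differed by 0.14 ± 0.25 and ARR15 by 0.03 ± 0.38, neither called. Among the 1428 probe sets called with either treatment at 12 h, the median size of the difference was 0.30, with a median half-width of the 95% interval of 0.47. For 1005 of them (70.4%) that interval excluded a 2-fold difference. In this design 55% of simulated 2-fold differences were recovered, but with 160 calls and so at a less strict threshold than with 1 call. That share overstates what could be recovered here. The count was 2 without estradiol 12 h replicate 1 and 5 without trans-zeatin 12 h replicate 1, 2 without a filter or without both arrays that stand apart, and 3 with the 3'/5' ratio as a covariate.

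At 24 h, 7 probe sets were called between the treatments, 2 of them higher with estradiol, with 892 at an unadjusted p under 0.05. The simulation recovered 45% of 2-fold differences, but with 148 calls and a less strict threshold, so that share is too high for this comparison. Higher with estradiol were 257039_at (101-fold, adjusted p = 1.8e-08) and AT5G59845, of the gibberellin-regulated GASA family, at a signal of 125 ± 47.9 with estradiol and 24.6 ± 3.58 with trans-zeatin (n = 2 each, log2 difference 2.04 ± 0.28, adjusted p = 0.021). Lower with estradiol were AT4G33980, the cold-regulated gene COR28 (-1.60 ± 0.25, adjusted p = 0.039), AT1G11210 (-1.60 ± 0.26, adjusted p = 0.049) and the unnamed 259990_s_at (-2.09), 263548_at (-1.62) and 262908_at (-1.27), chosen after their values were seen. ARR16 differed by 0.27 ± 0.27 and ARR15 by -0.06 ± 0.42, neither called. Among the 802 probe sets called with either treatment the median difference was 0.36 with a median half-width of 0.58, and for 419 (52.2%) the interval excluded a 2-fold difference. With each array centred on its median 2 were higher and 3 lower, and after quantile normalization 2 and 2. The count was 2 without estradiol 24 h replicate 2 or either trans-zeatin 24 h array, 4 without control replicate 1 or 2 of either time, and 15 without estradiol 12 h replicate 1. The call of AT5G59845 ended without estradiol 24 h replicate 2 (adjusted p = 0.47) or trans-zeatin 24 h replicate 1 (0.15) or 2 (0.27). The calls of AT4G33980 (8 arrays, adjusted p 0.058 to 0.7) and AT1G11210 (10 arrays, 0.06 to 0.7) ended without any 12 h control array, estradiol 12 h replicate 2 or any treated 24 h array, and that of AT1G11210 also without either control 24 h array. The count was 61 with only the 24 h arrays, 18 without both 12 h arrays that stand apart and 11 with the 25S rRNA signal as a covariate. It was 3 with the pseudocount at the 40th percentile and 2 without a filter, with the replicate block or with the 3'/5' ratio as a covariate. Without a filter or with the block the calls of AT5G59845 (adjusted p 0.072 to 0.091), AT4G33980 and AT1G11210 ended. Quantile normalization, the higher pseudocount or no intensity trend also ended those of AT4G33980 (0.061 to 0.11 over the 5 settings) and AT1G11210, which ended as well with centred arrays or without probe sets of shared sequence (0.052 to 0.13 over the 7). With the 3'/5' ratio as a covariate the changes of AT5G59845 (2.04 ± 0.30, adjusted p = 0.076), AT4G33980 (-1.61 ± 0.27, 0.1) and AT1G11210 (-1.51 ± 0.27, 0.11) stayed within 1 SE of those above, but none was called.

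The control groups were compared between the times. GI, a component of the circadian clock, rose 6.72-fold from 12 to 24 h, from a signal of 60.3 ± 19.4 (n = 3) to 427 ± 9.82 (n = 2; adjusted p = 0.0012). The chloroplast ribosomal protein gene rps15 rose 4.44-fold (log2 change 2.15 ± 0.26 SE, adjusted p = 0.0018), and AT4G16000 (1.93 ± 0.34), AT1G68250 (1.84 ± 0.28) and AT2G07708 (1.64 ± 0.30) rose. AT3G28550 (-2.26 ± 0.40), CHIL, a chalcone isomerase-like gene (-2.26 ± 0.41), AT3G13610, which acts in scopoletin synthesis (-1.84 ± 0.37), AT5G38020 (-1.72 ± 0.33) and AT3G57020 (-1.59 ± 0.23) fell. In all 73 probe sets were called, 28 higher and 45 lower, and 22 higher and 78 lower with each array centred on its median. An unadjusted p under 0.05 was found for 2338. The simulation recovered 42% of 2-fold changes, but with 142 calls and so at a less strict threshold. The actin 3'/5' ratio also differed, at 6.24 and 6.44 against 3.23 to 4.93. The count was 10 and 16 without control 24 h replicate 1 or 2, and 44 and 46 without control 12 h replicate 2 or 3. It was 48 without a filter, 46 without the intensity trend, 20 with the replicate block, 123 with the 25S rRNA signal and 14 with the 3'/5' ratio as a covariate. With the ratio GI alone of these 10 genes was called (adjusted p of the others 0.056 to 0.52). The changes of rps15 (2.1 ± 0.37), AT1G68250 (2.01 ± 0.39) and AT4G16000 (2.53 ± 0.43) were then as large or larger within their errors, with larger errors. Those of AT2G07708 (1.27 ± 0.40), AT3G28550 (-1.65 ± 0.52), CHIL (-1.62 ± 0.53), AT3G57020 (-1.04 ± 0.23), AT5G38020 (-0.80 ± 0.30) and AT3G13610 (-0.78 ± 0.32) were smaller. The replicate block ended the calls of AT2G07708 (adjusted p = 0.11), AT3G28550 (0.062), AT3G13610 (0.11), AT5G38020 (0.11) and CHIL (0.097). No filter or no intensity trend ended those of the same 5 genes (0.05 to 0.084), and no trend also that of AT4G16000 (0.053). Only the control arrays ended those of AT1G68250, AT3G13610, AT4G16000, AT5G38020 and CHIL (0.058 to 0.12). Leaving out both arrays that stand apart ended those of AT2G07708, AT3G13610 and AT3G28550 (0.062 to 0.07), quantile normalization that of AT3G13610 (0.054), the higher pseudocount that of CHIL (0.075) and the 25S rRNA signal that of AT4G16000 (0.1). Without either control 24 h array the calls ended of AT4G16000 (adjusted p 0.18 to 0.21), AT1G68250 (0.095 to 0.19), CHIL (0.16 to 0.23) and AT3G57020 (0.092 to 0.11), and without control 24 h replicate 1 that of rps15 (0.055). Those of AT2G07708 (any array of the 2 groups, 0.055 to 0.27), AT3G28550 (control 12 h replicate 2 or 3, either control 24 h array, 0.053 to 0.22), AT3G13610 (the same 4 arrays, estradiol 12 h replicate 2 or 3, or any treated 24 h array, 0.055 to 0.29) and AT5G38020 (either control 24 h array, estradiol 12 h replicate 2, or any treated 24 h array, 0.051 to 0.26) ended too.

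Whether the effect of a treatment differed between 24 and 12 h was tested as an interaction. For estradiol, 12 probe sets were called, 4 with a higher and 8 with a lower change at 24 h (6 and 7 with each array centred on its median). AT4G33980 changed by 0.63 ± 0.20 SE at 12 h and by -1.68 ± 0.25 at 24 h (difference -2.31 ± 0.32, adjusted p = 0.011), and AT1G11210 by 0.11 ± 0.21 and -2.21 ± 0.26 (difference -2.32 ± 0.33, adjusted p = 0.012). The other 10 have no gene named; the largest differences, chosen after the values were seen, were those of 261569_at (-1.17 at 12 h, 3.29 at 24 h) and 267364_at (0.82 and -3.45). For trans-zeatin limma called 0 probe sets, with 1487 at an unadjusted p under 0.05. The simulation recovered 83% of 4-fold and 16% of 2-fold differences, but with 108 calls and a less strict threshold, so both shares are too high here. ARR16 (0.52 ± 0.35 and 0.40 ± 0.37) and ARR15 (1.03 ± 0.54 and 1.11 ± 0.57) did not pass for estradiol or trans-zeatin. The estradiol count was 3 and 5 without control 24 h replicate 1 or 2, 6 without estradiol 24 h replicate 2, 20 without estradiol 12 h replicate 1, 19 without both arrays that stand apart or with the 25S rRNA signal as a covariate, and 30 with the 3'/5' ratio as a covariate. The trans-zeatin count was 1 without control 12 h replicate 1 or trans-zeatin 12 h replicate 1, and 6 with the 3'/5' ratio as a covariate. The call of AT4G33980 ended without control 24 h replicate 1 or estradiol 24 h replicate 2 (adjusted p 0.072 to 0.073), and that of AT1G11210 without any control or estradiol 24 h array (0.051 to 0.11).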

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

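The tests of the chloroplast transcripts, the sign test of the 24 h calls and the fit with the 3'/5' ratio as a covariate were chosen only after the data were seen. The effect of estradiol differed between 24 h and 12 h in 12 probe sets by the interaction test, among them AT4G33980 (log2 difference -2.31) and AT1G11210 (-2.32). These stand out because 2 time points gave different effects under the same contrast. The clock gene GI rose 6.72-fold between the controls, and the samples are described by hours of treatment only. Length of treatment and time of day can therefore not be told apart here. AT4G33980 had a mean signal of 82.7 with estradiol at 12 h (control 51.5) and 24.5 at 24 h (control 95.6), and AT1G11210 of 133 (control 121) and 37.8 (control 198).

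The 762 calls of estradiol 12 h against control were set against the 10 splits of the same 6 arrays into groups of 3. The real split was the only 1 with as many calls, and the highest of the others gave 0; with 10 splits the smallest possible share is 0.1, too few for a share under 0.05.

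The calls at 24 h coincide with a higher actin 3'/5' ratio in the 24 h controls, so RNA quality is a candidate explanation beside the treatment. Whether a linear trend with the ratio is the whole cause of the estradiol calls could not be decided by taking it as a covariate. The covariate was the mean log2 ratio of actin, GAPDH and ubiquitin, not the actin ratio alone. With group means fitted, its slope came only from differences within groups, and the control 24 h arrays were close (actin ratio 6.24 and 6.44). An imprecise slope can leave changes near their full size. With this covariate, the log2 changes of the 595 estradiol 24 h calls kept a median of 0.962 of their size (quartiles 0.846 to 1.07). Fewer calls passed then (349), as the median SE went from 0.275 to 0.306 and the median size from 1.40 to 1.35; for trans-zeatin 24 h, calculated later, 176 probe sets passed against 541 before, the median share of the size was 0.917 (quartiles 0.75 to 1.09), the median SE went from 0.276 to 0.353 and the median size from 1.46 to 1.34. Of the estradiol 24 h calls 86.6%, and of the trans-zeatin 24 h calls 94.3%, had the same sign with that treatment at 12 h on other arrays, but the ratio was higher in the controls there too, so the shared sign leaves RNA quality open. The actin ratios of the treated 24 h arrays (3.71 to 4.85) overlapped those of the control 12 h arrays (3.23 to 4.93). On the first principal component the former lay from 12.28 to 23.79 and the latter from -30.72 to -28.73, with the control 24 h arrays at -42 and -42.28. These values argue against the actin ratio as the whole source of that separation. They do not exclude a part of RNA quality in the 24 h calls. The treatments themselves, which the design names, remain an open explanation that these tests do not address.

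Transcripts of 61 chloroplast-encoded genes had a median log2 value 0.86 higher with estradiol than with trans-zeatin at 24 h, relative to the median of all probe sets, and 0 of the 61 were called between the treatments; against control the medians were 0.59 with estradiol (3 higher, 0 lower, adjusted p = 5.2e-10; adjusted p = 0.6 with an estimated correlation) and -0.26 with trans-zeatin (0 higher, 3 lower, adjusted p = 0.077), where at 12 h it was 0.19 with trans-zeatin (2 higher, 0 lower, adjusted p = 0.045; adjusted p = 0.9 with an estimated correlation) and 0.11 with estradiol (adjusted p = 0.25), and between the controls, 24 h against 12 h, 0.24 (adjusted p = 0.0093; adjusted p = 0.85 with an estimated correlation). Between the treatments the list test gave adjusted p = 5e-38 at the preset correlation and adjusted p = 0.47 with an estimated correlation, so the shift may be a variation shared by all these transcripts. A single estradiol 24 h array as a source stays open: the median over genes of the difference was 1.00 and 0.643 with either array alone. The spread was taken from another measure, the chloroplast median of each array (7.91 and 8.35 with estradiol 24 h, 7.33 and 7.46 with trans-zeatin 24 h). These medians had a pooled SD of 0.23 (SE 0.28 for 1 array against 2), and arrays of 1 group differed by up to 0.62 (trans-zeatin 12 h). Carry-over of RNA without a poly(A) tail stays open: over the 14 arrays the chloroplast median and the 25S rRNA signal had r = 0.2 (permutation p = 0.49; rho 0.059, permutation p = 0.84; r = 0.028 over 12 arrays without the 2 farthest), and r = -0.67 within groups. A difference between the treatments was not tested apart from the arrays that carry it.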

How the results depend on the processing

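The settings that leave out both 12 h arrays that stand apart, or take the 3'/5' ratio or 25S rRNA signal as a covariate, were chosen after seeing the data. No called change reversed its direction in the 27 alternatives run for genes and the 28 run for lists, although the stricter filter covered only 78 of the 98 gene and 8 of the 36 list results, the arrays of the time point 96 and the removal of shared probe sets 97 of the gene results; changes of sign in values called in neither setting were not counted. Of 2623 alternative values for 98 gene results, 2371 kept their direction and side of the threshold, 231 lost the call and 21 gained it; of 980 for 36 list results, 955, 15 and 10. Of 82 called named changes, 49 were kept without each single array and 51 under every other setting. Where an array was left out of 2, the lone array is assumed to vary like the other groups. No probe set is named for IPT8, so its level was not read, and dim signals near the pseudocount of 6.3 limit all folds. Without single arrays, the counts ranged from 417 to 964 (estradiol 12 h), 264 to 1373 (trans-zeatin 12 h), 198 to 732 (estradiol 24 h), 164 to 658 (trans-zeatin 24 h), 1 to 5 and 2 to 15 (between treatments at 12 h and 24 h), 10 to 93 (between controls), 3 to 20 (estradiol interaction) and 0 to 1 (trans-zeatin interaction). Shared calls ranged from 197 to 555 (both treatments at 12 h), 141 to 402 (both at 24 h), 118 to 299 (estradiol at both times), 133 to 352 (trans-zeatin at both times), 113 to 289 (estradiol 12 h with trans-zeatin 24 h) and 124 to 346 (trans-zeatin 12 h with estradiol 24 h). The lateral root founder median ranged from -0.94 to -0.66 at estradiol 12 h and from -1.27 to -0.99 at trans-zeatin 12 h, and the mitosis median from -0.91 to -0.55 at estradiol 24 h. Between treatments at 24 h, 4 probe sets were called after quantile normalization, 3 with the pseudocount at the 40th percentile, and 2 without a filter or with the replicate block. Without a filter, 2 were called between treatments at 12 h and 48 between controls. Between controls, 46 were called without the intensity trend and 20 with the replicate block; the block gave 656, 832, 498 and 471 against control (estradiol and trans-zeatin at 12 h, then 24 h). At least 2-fold left 348 at estradiol 12 h, 554 at trans-zeatin 12 h and 250 shared at 12 h, by its construction. With only the arrays of the time point, counts were 332, 500, 1158 and 942 against control and 61 between treatments at 24 h, with 222 and 620 shared at 12 h and 24 h. Without both 12 h arrays that stand apart, counts were 426 (estradiol 12 h), 939 (estradiol 24 h), 822 (trans-zeatin 24 h), 2 and 18 between treatments and 19 for the estradiol interaction, with 331 shared at 12 h and 524 at 24 h. With the 3'/5' covariate, counts were 355, 112, 349 and 176 against control, 3 and 2 between treatments, 14 between controls, and 30 and 6 for the interactions; shared calls were 99, 140, 138, 69, 107 and 70 in the order above. The median SE of the calls then went from 0.198 to 0.245, 0.221 to 0.359, 0.275 to 0.306 and 0.276 to 0.353. With the 25S covariate, counts were 521 (trans-zeatin 12 h), 11 (between treatments at 24 h), 123 (between controls) and 19 (estradiol interaction), with 329 shared at 12 h. The lateral root founder list at trans-zeatin 12 h lost its call without a pseudocount (-1.31), with the 3'/5' covariate (-0.757), with the 25S covariate (-0.949) and with an estimated correlation (-1.1), which also ended its calls at estradiol 24 h (-1.48) and trans-zeatin 24 h (-1.9) and that of the type-A response regulators at trans-zeatin 12 h (1.89). At estradiol 12 h it gained a call with the pseudocount at the 40th percentile (-0.589), without a filter (-0.772), with the arrays of the time point (-0.772) and without both arrays that stand apart (-1.06), as did the mitosis list at trans-zeatin 12 h without a filter (-0.764). Except where stated, the cause was not tested.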

Other observations

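The families named here and their tests were chosen after the results were seen; the tests of neighbouring genes were fixed before their counts were seen. Of 39 measured genes of cytosolic ribosomal proteins, 10 fell and 0 rose with estradiol at 12 h, and 12 fell and 0 rose with trans-zeatin, while 29 and 27 were not called. The median log2 changes relative to all probe sets were -0.38 and -0.44 (adjusted p = 6.9e-14 and 2.4e-13 at the preset correlation; adjusted p = 0.6 in both with an estimated correlation). AT1G07070 fell by 0.85 with estradiol at 12 h and AT2G17360 by 0.84 with trans-zeatin. At 24 h, 1 fell with estradiol (median relative to all probe sets -0.18, adjusted p = 1e-04; adjusted p = 0.71 with an estimated correlation) and 0 with trans-zeatin (-0.043, adjusted p = 0.25); whether the effect differed between the times was not tested for the family. The medians at 12 h were also negative under quantile normalization (-0.34 and -0.48) and with each array centred on its median (-0.38 and -0.42). In these comparisons the 3'/5' ratio was higher in the controls.

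Class III peroxidases, secreted enzymes that act on cell walls and on hydrogen peroxide, went both ways. Of 43 measured, 2 rose and 4 fell with estradiol at 12 h, 3 rose and 11 fell with trans-zeatin at 12 h, 3 and 6 with estradiol at 24 h, and 4 and 5 with trans-zeatin at 24 h. The family medians relative to all probe sets were -0.27, -0.27, -0.03 and 0.08. The family test did not pass (camera adjusted p 0.077, 0.11, 0.52 and 0.92), which leaves a shift down at 12 h open. AT2G34060 rose in all 4 comparisons (log2 1.86, 1.97, 1.32 and 1.62), while AT4G33420 (-1.45, -1.50, -1.34 and -1.37) and Prx37 (-1.17, -1.88, -1.18 and -1.48) fell in all 4. Of 11 genes of autophagy proteins, 2 rose with trans-zeatin at 12 h (family median relative to all probe sets 0.58, camera adjusted p = 0.0031, or 0.61 with an estimated correlation). In the other 3 comparisons with control 0 were called (camera adjusted p at least 0.79). Between estradiol and trans-zeatin at 12 h the family median relative to all probe sets was -0.39, with 0 called (camera adjusted p = 3.2e-05, or 0.6 with an estimated correlation). Of 8 genes of NPF transporters, which carry nitrate, peptides or hormones, 2 rose with estradiol at 24 h. Their family median relative to all probe sets was 1.04 (camera adjusted p = 0.0021, or 0.52 with an estimated correlation). On the same measure it was 0.33 with estradiol at 12 h (1 rose, camera adjusted p = 0.11). With trans-zeatin it was 0.30 at 12 h and 0.60 at 24 h (0 called, camera adjusted p = 0.35 and 0.25).

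Genes called higher in at least 1 of the 4 comparisons with control lay next to each other on the chromosome in 18 pairs, such as AT3G28310 and AT3G28320, JAL33 and JAL34, and AT5G64110, AT5G64120 and AT5G64130. Chance order is argued against: over 383 such genes among 8276 with 2821 adjacent pairs, 10000 random placements gave a mean of 6.05 and at most 16 (permutation p = 1e-04, the smallest they can give). Genes called lower gave 18 pairs among 527 against a mean of 11.4 (share of placements 0.04). Signal shared between near-identical neighbours may contribute and stays open: without probe sets of shared sequence the count was 18 again, but that filter removed none of the genes in these pairs, so the limit set for it before the count was seen was wrong, as it could not separate the explanations. Regulation of neighbouring copies together was not tested.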
